A study of Mus musculus with 21 samples.

How the data were processed

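Gene expression was measured with biotin-labelled RNA on Affymetrix arrays in 21 samples, 3 biological replicates in each of 7 groups of sorted mouse monocytes and macrophages. Per the labels, peritoneal cells were collected by lavage and bone marrow by flushing, and cells were stained on ice and purified on a cell sorter, RNA was extracted with TriZol, and 100 ng was amplified and labelled in 2 cycles. The deposited values are MAS5 signal intensity on a linear scale, made by the authors in Affymetrix Expression Console 1.2 with each array scaled. The 2% trimmed mean over all probe sets was 500.0 in each array, tested on the values. The table held 45101 probe sets and 21 columns, with 0 columns unmatched to a sample. Values ran from 0.0638 to 49770, and the 15 added before the logarithm limits the fold change of a gene near the floor. Detection calls, raw image files and genome positions were not used here.

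Signals were taken as log2(value + 15), where 15 is the 20th percentile of all values, rounded. Probe sets with 1 gene symbol in the annotation numbered 34958. Those with several symbols (932) and those not listed (9211) were left out, since their gene is not known. Each of 18193 genes was represented by its probe set with the highest mean over all arrays, and genes with a signal above 80.6, the median of the table, in at least 3 arrays were tested, 12154 in all. Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a trend) over all 21 arrays, which left 14 residual degrees of freedom. A gene was called with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested and an absolute log2 fold change of at least 1. There were 6 main and 4 secondary comparisons, and an F test over the 7 groups. Tests were 2-sided.

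A total of 30 gene lists were written before the data were examined, 18 of processes and 12 of sample quality or other cell types. They held 591 entries, 59 of them not analysed here for want of a probe set assigned to that gene alone. The process lists were DNA replication, mitosis, resident macrophage, classical monocyte, MHC class II, inflammatory mediators, interferon response, alternative activation, apoptotic cell uptake, cholesterol synthesis, glycolysis and hypoxia, respiratory chain, lysosome, growth factors and matrix, chemoattractant receptors and adhesion, pattern recognition, eicosanoids, and macrophage growth receptors. The other lists were handling stress, ribosomal proteins, neutrophils, granulocyte and monocyte progenitors, B cells, T and NK cells, mast cells, eosinophils, dendritic cells, mesothelial cells or fibroblasts, erythroid cells and platelets. Some genes stood in several lists, so that calls of those lists are not independent. Chil3 was in the classical monocyte and alternative activation lists, and Ccr2 in the classical monocyte and chemoattractant receptor lists. The 28 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation stands beside each call, and 21 of 110 list calls held with it.

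Genes were named by a rule fixed before the data were examined. It takes the 6 genes with the largest change in each direction in a main comparison and the 3 in a secondary one, among called genes whose arrays do not overlap. It adds the 2 members with the largest change (1 in a secondary comparison) of each called process list, the largest called member in the other direction in a main comparison, up to 3 abundant members of each called quality or cell type list, and 20 reference genes. Not all of these genes are named, and 1 reference gene is not reported here. Per-array signals are also given for markers chosen after their values were seen, and so are the changes of Atf3, Nr4a1 and Hsph1.

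The thresholds, the lists, the comparisons and the alternatives were chosen before the data were examined, except where said otherwise. The alternatives were a pseudocount of 1 and of 4 times the value used, quantile normalization, a common array median, no filter and a filter at the 75th percentile, the mean of a gene's probe sets and all probe sets, eBayes without the trend, array weights, the replicate block, the Gapdh 3'/5' ratio as a covariate, no minimum fold, limma's treat, only the 6 arrays compared, and each replicate left out in turn. Replicate numbers were taken to pair arrays where the residuals of arrays with the same number correlated above 0.1 for all 3 numbers, which held for the groups of 168 h alone. Weaker structure by number was seen elsewhere. In resident against bone marrow, 72 h against 18 h and Ly-6B- against resident, 6 of 6 arrays correlated best with their own number. The control probe sets bioB had a mean of 805 for number 3, against 672 and 666 for numbers 1 and 2. Its source was not tested. On simulated data of the same size, changes of 1.5, 2 and 3 on the log2 scale were recovered in 581 of 670, 640 of 670 and 655 of 660 genes, with 34 false calls over 10 comparisons. A shifted list was called in 10 of 10 comparisons with 1 other list called. Genes were simulated independently of each other, so this does not show how often lists of correlated genes are called falsely.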

Results

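Gene expression was measured on Affymetrix arrays in 21 samples of sorted mouse cells, 3 arrays in each of 7 groups. Peritonitis was started by an injection of zymosan, a yeast cell wall preparation that phagocytes take up, into the peritoneal cavity of female C57BL/6 mice. Cells sorted at 4 h were Ly-6B+ and Ly-6G-, and those at 18 h also included cells low in Ly-6B. Macrophages of 72 h were F4/80+ and CD11b+. At 168 h the macrophages were sorted into a Ly-6B+ group with medium to high F4/80 and a Ly-6B- group with high F4/80. Naive mice gave the reference groups, Ly-6B+ Ly-6G- bone marrow monocytes and resident peritoneal macrophages high in F4/80 and CD11b. Median signal per array ran from 67.3 to 93.0 over 45101 probe sets, and the number of arrays limits the precision of each value. Arrays of one group correlated with each other at a mean r of 0.969 to 0.980 across genes, which are not independent replicates. Of 12154 genes tested, 8477 (69.7%) differed between the groups in limma's F test over all 7 groups. The first principal component held 48.5% of the variance and the second 22.5%.

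**Figure D1:**
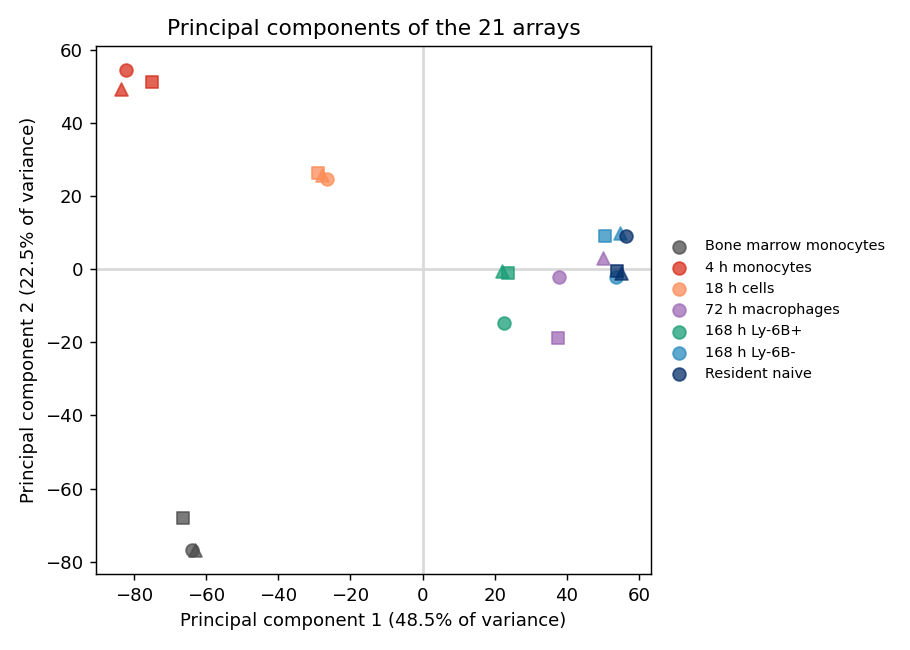
Principal components of the log2 signals of 12154 genes, the first component (48.5% of the variance) on the horizontal axis and the second (22.5%) on the vertical axis, 1 point per array, a colour for the group and a marker shape for the replicate number. The bone marrow, 4 h and 18 h arrays lie apart from those of 72 h, 168 h and resident macrophages.

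Reference genes were followed through all groups. Values are MAS5 signals as mean ± SD of 3 arrays. Timd4, a receptor for phosphatidylserine on resident macrophages, had a signal of 18633 ± 532 (SD, n = 3) in resident macrophages and 3.52 ± 1.60 in bone marrow monocytes. It stood at 96.0 ± 87.2 at 4 h, 347 ± 107 at 18 h, 13914 ± 2274 at 72 h, 16913 ± 519 in Ly-6B- and 1622 ± 449 in Ly-6B+ macrophages at 168 h. Ccr2, the monocyte chemokine receptor, was 12011 ± 2050.5 in bone marrow, 16491 ± 940.3 at 4 h, 16253 ± 2503 at 18 h and 5288 ± 2687 at 72 h. Its signal was 6848 ± 1173 in the Ly-6B+ and 160.0 ± 65.4 in the Ly-6B- macrophages of 168 h and 182 ± 118 in resident macrophages. Mki67, a proliferation marker, was 20652 ± 2995 in bone marrow, 221 ± 30.9 at 4 h, 432 ± 49.1 at 18 h and 6229 ± 4729 at 72 h. At 168 h it was 4317 ± 2111 in Ly-6B+ and 1922 ± 1358 in Ly-6B- macrophages, and it was 2249 ± 1460.1 in resident ones. Adgre1, which encodes F4/80, measured 4476 ± 902 in bone marrow, 8055 ± 182 at 4 h, 16810.5 ± 291 at 18 h and 32439.5 ± 2386 at 72 h. It measured 22914 ± 1613 in Ly-6B+, 35755 ± 1596 in Ly-6B- and 35564 ± 1566 in resident macrophages. The cytokine gene Il10 ran from 10.6 ± 6.47 in bone marrow, its lowest mean, to 137 ± 24.3 in Ly-6B- macrophages, its highest. Ly6c1 and Ly6g were not analysed here.

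**Figure D2:**
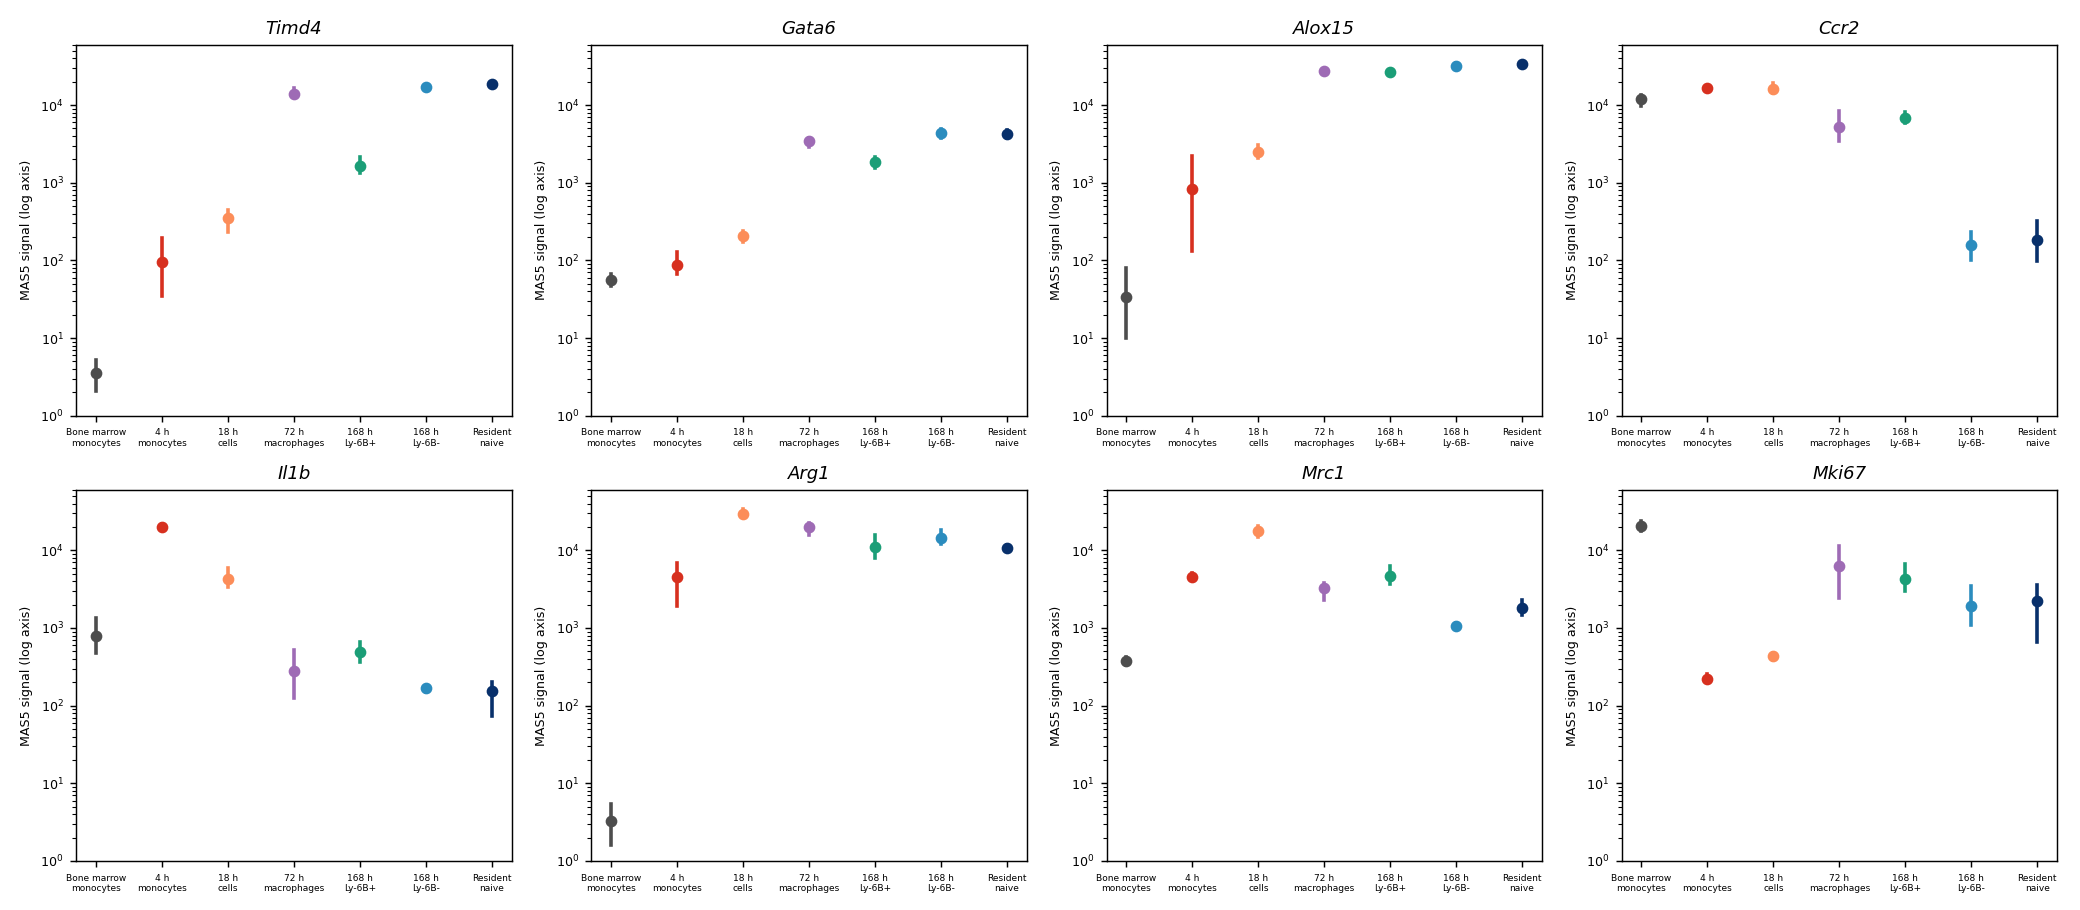
MAS5 signal on a log axis for 8 reference genes in the 7 groups, a point for the mean and a bar from the lowest to the highest of 3 arrays. Timd4 reaches 18633 ± 532 in resident macrophages, and Ccr2 separates the Ly-6B+ (6848 ± 1173) from the Ly-6B- macrophages (160.0 ± 65.4) at 168 h.

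**Figure D3:**
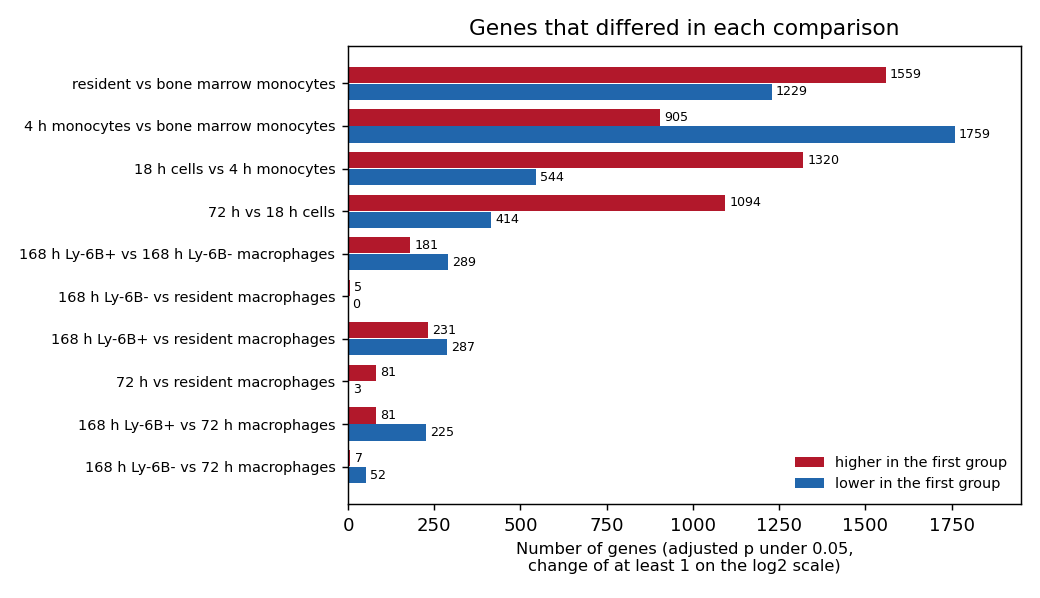
Number of genes called higher and lower in each of the 10 comparisons, 1 pair of bars per comparison from 0. The counts reach 1559 higher and 1229 lower for resident macrophages against bone marrow monocytes and come to 5 and 0 for Ly-6B- macrophages of 168 h against resident macrophages.

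Resident peritoneal macrophages were compared with bone marrow monocytes to set the distance between the reference populations. The largest increases in resident macrophages were in the complement genes C1qc and C1qa, in Ptgis, the prostacyclin synthase, and in Timd4. C1qc measured 29817 ± 3532 against 3.74 ± 1.02 (log2 fold change 10.63, adjusted p = 9.84e-17) and C1qa 28728 ± 2123 against 6.95 ± 2.16. Ptgis measured 25947 ± 639 against 9.34 ± 2.95, and the scavenger receptor gene Marco 16005 ± 1065 against 4.23 ± 1.42. Among the largest decreases, Camp, which encodes cathelicidin, fell by 9.06 on the log2 scale. Mpo, myeloperoxidase, was 52.1 ± 20.8 against 21830.2 ± 11103 and Ctsg, cathepsin G, 21.2 ± 12.4 against 11382 ± 5399. The receptor gene Met was 2.15 ± 0.872 in resident macrophages and 4213 ± 346 in bone marrow monocytes. In all, 1559 genes were higher and 1229 lower in resident macrophages, and the arrays of both groups did not overlap for 56% of genes tested, where chance gives 10%.

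All 20 measured genes of the resident peritoneal macrophage list rose (camera adjusted p = 3.71e-22, and adjusted p = 0.0254 with an estimated correlation), with Alox15, a lipoxygenase, at 33569 ± 2378 against 33.4 ± 40.0. Genes of apoptotic cell uptake and scavenger receptors rose in 16 of 24 and fell in 4, Itgb5 among them with a log2 change of -2.03 (camera adjusted p = 5.72e-06, and adjusted p = 0.0339 with an estimated correlation). Among lysosomal genes 5 of 22 rose, with Glb1, beta-galactosidase, at 7735 ± 418 against 926 ± 56.8 and Ctsd, cathepsin D, at 22893 ± 1511 against 4016 ± 511 (camera adjusted p = 4.25e-04, and adjusted p = 0.101 with an estimated correlation). Alternative activation genes rose in 6 of 16 and fell in 2 (camera adjusted p = 0.0129, and adjusted p = 0.135 with an estimated correlation). Arg1, arginase, measured 10820.4 ± 682 against 3.24 ± 1.98 and Retnla 7750.4 ± 3238 against 34.1 ± 18.0, whereas Chil3 was 285 ± 67.5 against 30178 ± 3718. The list of growth factors and matrix genes had 8 of 21 higher and 2 lower (camera adjusted p = 0.00928, and adjusted p = 0.0925 with an estimated correlation). Its member Tgfb2 was 13904 ± 1265 against 30.9 ± 11.1 and Ecm1 27505 ± 1505 against 217 ± 11.1, while Mmp8, a collagenase, changed by -4.98. Pattern recognition receptors rose in 9 of 21, led by Clec4d (log2 fold change 4.78) and Tlr3 (3.26), with Nlrp3 alone lower at -1.36 (camera adjusted p = 0.0172, and adjusted p = 0.0925 with an estimated correlation). Of the eicosanoid genes 7 of 14 rose and 3 fell, Hpgd, which inactivates prostaglandins, by a log2 change of -3.15 (camera adjusted p = 0.0129, and adjusted p = 0.0945 with an estimated correlation).

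Lower in resident macrophages were 29 of 29 mitosis genes (camera adjusted p = 2.96e-13, and adjusted p = 0.24 with an estimated correlation) and 25 of 29 DNA replication genes (camera adjusted p = 5.71e-11, and adjusted p = 0.24 with an estimated correlation). Bub1b, a spindle checkpoint kinase, measured 441 ± 243 against 5688 ± 472, and Rrm2, a subunit of ribonucleotide reductase, 753 ± 463 against 9692 ± 2809. Classical monocyte genes fell in 9 of 14, Ms4a4c from 15069.7 ± 2381 to 88.7 ± 42.6, and Clec4e alone rose, from 1988 ± 565 to 8059 ± 537 (camera adjusted p = 1.21e-04, and adjusted p = 0.0174 with an estimated correlation). Cholesterol synthesis genes fell in 7 of 18, with Fdft1, squalene synthase, at -2.09 and Sqle, squalene epoxidase, at -1.91 (camera adjusted p = 0.0129, and adjusted p = 0.421 with an estimated correlation). Interferon-stimulated genes fell in 7 of 22, Ifit2 by a log2 change of -4.16, and rose in 2, Gbp2 by 2.07 (camera adjusted p = 0.048, and adjusted p = 0.652 with an estimated correlation). That list's adjusted p was 0.0816 after quantile normalization. Counts adjusted over the list alone were the same as over all genes for each list named in this comparison.

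Markers of other bone marrow cells moved with this contrast, although the bone marrow sort was gated Ly-6B+ and Ly-6G-, a gate meant to leave out neutrophils. Neutrophil genes fell in 9 of 14 (camera adjusted p = 1.05e-04, and adjusted p = 0.0925 with an estimated correlation), and granulocyte and monocyte progenitor genes in 10 of 12 (camera adjusted p = 1.59e-06, and adjusted p = 0.0925 with an estimated correlation). S100a8 was 31508 ± 10842 in bone marrow monocytes, while Lrg1 of the neutrophil list rose to 14766 ± 2061 in resident macrophages. Bone marrow replicate 3 had an S100a9 signal of 39146 beside 8538 and 5796 in the other arrays, and an Mpo signal of 33879 beside 19598 and 12013. Where a group's signal is near the floor of the array, the fold change depends on the 15 added before the logarithm.

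Monocytes in the cavity at 4 h were compared with bone marrow monocytes. The groups differed in tissue and in zymosan, and may differ in the cells sorted. These differences cannot be told apart from a change on entry into the inflamed site. The bone marrow arrays had Mpo signals of 19598, 12013 and 33879 and Mki67 signals of 20868, 17555 and 23533, so high levels were not confined to replicate 3. Arg1 measured 4556 ± 2459 against 3.24 ± 1.98 (log2 fold change 7.79, adjusted p = 9.99e-14), and Tgm2, a transglutaminase, 21576 ± 2008 against 107 ± 56.8. Serpinb2, an inhibitor of plasminogen activators, was 6199.8 ± 857 against 24.4 ± 3.36, and Acod1, which makes itaconate, 3503 ± 1953 against 19.5 ± 21.9. Dab2, an endocytic adaptor gene, reached 8968 ± 1319 with a log2 fold change of 7.21. Bub1b stood at 5.20 ± 1.58 against 5688 ± 472 (log2 fold change -8.14), Nuf2, a kinetochore gene, at 5.52 ± 3.21 against 2637 ± 325, and Mpo at 81.0 ± 10.6 against 21830.2 ± 11103. At 4 h 905 genes were higher and 1759 lower, and 54.7% of genes had arrays that did not overlap, against 10% by chance. Array medians over the genes tested were 0.36 lower on the log2 scale at 4 h (-0.36) and the median gene changed by -0.14, so that with each array set to a common median the counts were 1598 higher and 1110 lower.

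Of the inflammatory cytokines, chemokines and enzymes 19 of 22 rose (camera adjusted p = 4.34e-12, and adjusted p = 0.0614 with an estimated correlation). The chemokine gene Cxcl3 was 4343 ± 619.9 against 17.6 ± 12.2 and Il1rn, the interleukin-1 receptor antagonist, 12119 ± 694 against 201 ± 27.3. Pattern recognition receptors rose in 12 of 21 (camera adjusted p = 1.87e-11, and adjusted p = 1.72e-04 with an estimated correlation), among them the C-type lectins Clec4n (log2 fold change 5.28) and Clec4d (4.90). Alternative activation genes rose in 10 of 16 (camera adjusted p = 1.14e-07, and adjusted p = 0.00721 with an estimated correlation). Genes of apoptotic cell uptake rose in 14 of 24, with C1qc at 816 ± 549 against 3.74 ± 1.02 (camera adjusted p = 1.14e-07, and adjusted p = 0.00961 with an estimated correlation). C1qc stood at a median of 2.15% of the level in resident macrophages. It is among the transcripts used to gauge carried resident cells, and its signal was 1429.8 in 4 h replicate 2 beside 645 and 372. In the list of growth factors and matrix genes 10 of 21 rose and 2 fell (camera adjusted p = 3.49e-07, and adjusted p = 0.00531 with an estimated correlation). Mmp19 was 2256 ± 286 against 14.4 ± 15.1, Timp1, an inhibitor of metalloproteinases, 4503 ± 772 against 61.7 ± 16.7, and Vegfb 17.4 ± 15.4 against 74.2 ± 24.3. The Vegfb call was lost in 1 of 19 alternatives. Chemoattractant receptors and adhesion genes rose in 8 of 22 and fell in 5 (camera adjusted p = 0.0012, and adjusted p = 0.0475 with an estimated correlation). The complement receptor genes C3ar1 and C5ar1 changed by 5.42 and 4.62, and Cxcr4, a receptor that retains cells in bone marrow, by -2.65.

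Glycolysis and hypoxia genes rose in 9 of 21, with Slc2a1, a glucose transporter, at 8079 ± 928 against 1021 ± 176 (camera adjusted p = 1.32e-04, and adjusted p = 0.0475 with an estimated correlation). Cholesterol synthesis genes rose in 9 of 18 and fell in 2 (camera adjusted p = 3.92e-04, and adjusted p = 0.165 with an estimated correlation), Cyp51 by a log2 change of 2.63 and Sqle by 2.34. Genes of MHC class II presentation rose in 7 of 14, H2-Ab1 from 909.9 ± 104 to 5000.0 ± 501 (camera adjusted p = 1.12e-04, and adjusted p = 0.108 with an estimated correlation). Interferon-stimulated genes rose in 9 of 22 and fell in 2 (camera adjusted p = 0.00284, and adjusted p = 0.4 with an estimated correlation), with Zbp1 at 1.79 and Cmpk2 at -2.23. Adjusted over the list alone, 3 of them fell and 9 rose. Receptors and transcription factors of macrophage growth rose in 7 of 23 and fell in 3 (camera adjusted p = 0.00154, and adjusted p = 0.103 with an estimated correlation), with Maf at 11700.4 ± 2644 against 515 ± 84.9 and Klf4 at 6331 ± 1241 against 25809 ± 2146. Classical monocyte genes rose in 3 of 14 and fell in 2 (camera adjusted p = 0.0363, and adjusted p = 0.103 with an estimated correlation), with Vcan, versican, at 3.90 and Cx3cr1 at -1.32. Cx3cr1 lost its call in 2 of 20 alternatives. Lysosomal genes rose in 2 of 22, Ctsl, cathepsin L, by 2.39 (camera adjusted p = 0.0363, and adjusted p = 0.296 with an estimated correlation). After quantile normalization the adjusted p was 0.0882 for the classical monocyte list and 0.112 for the lysosomal list.

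All 29 measured mitosis genes fell (camera adjusted p = 3.96e-17, and adjusted p = 0.136 with an estimated correlation), Top2a, a topoisomerase, from 15076 ± 1130.4 to 108 ± 27.0. DNA replication genes fell in 28 of 29, Rrm2 from 9692 ± 2809 to 70.3 ± 15.6 and Tk1, thymidine kinase, from 2196 ± 479.6 to 23.7 ± 4.92 (camera adjusted p = 3.80e-16, and adjusted p = 0.127 with an estimated correlation). Progenitor genes fell in 9 of 12, Prtn3 from 14664 ± 5693 to 854 ± 107 (camera adjusted p = 6.29e-05, and adjusted p = 0.127 with an estimated correlation). S100a9, Camp, Mpo and Elane, followed per array, were each lower in every 4 h array than in every bone marrow array. S100a9 was 8538, 5796 and 39146 in bone marrow and 152, 86.6 and 159 at 4 h. The resident macrophage list rose in 11 of 20 and fell in 2 (camera adjusted p = 1.44e-06, and adjusted p = 0.146 with an estimated correlation), with Cxcl13, a chemokine, at 1118 ± 624 against 39.0 ± 17.4 and Itga6, an integrin, at 287 ± 215 against 636 ± 97.8. The call of Itga6 was lost in 2 of 20 alternatives. Beside this list, 4 h replicate 2 had an Alox15 signal of 2199.8 against 131 and 156 in the other 4 h arrays. With bone marrow replicate 3, 4 h replicate 2 and 72 h replicate 2 left out, a choice made after seeing the data, the classical monocyte and lysosomal lists had an adjusted p of 0.0582 and 0.0724. Other lists named in this comparison had the same counts adjusted over the list alone.

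Cells of 18 h were compared with monocytes of 4 h, for the change within the first day of inflammation. The gate at 18 h also took cells low in Ly-6B, so time and gate cannot be told apart. Ltc4s, the leukotriene C4 synthase, measured 3116 ± 749 at 18 h against 71.6 ± 68.6 at 4 h (log2 fold change 5.46, adjusted p = 1.41e-09). Cbr2, a carbonyl reductase, was 8859.6 ± 905 against 311 ± 105, Folr2, a folate receptor, 2792 ± 305 against 129 ± 49.8, and the glucose-responsive transcription factor gene Mlxipl 2372 ± 1028 against 85.3 ± 92.8. Inhba, an activin subunit, fell by 4.83 on the log2 scale, to 12.4 ± 2.93. Mmp8 stood at 210.4 ± 48.2 against 6101 ± 51.5, Arg2 at 78.1 ± 33.1 against 2249.9 ± 409, and Il1rn at 477 ± 84.4 against 12119 ± 694. In all, 1320 genes were higher and 544 lower at 18 h, and the arrays did not overlap for 50% of genes, where chance gives 10%. Array medians were 0.29 higher at 18 h on the log2 scale and the median gene changed by 0.14. With each array set to a common median, the counts were 731 higher and 985 lower.

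Inflammatory mediators fell in 12 of 22 (camera adjusted p = 3.46e-06, and adjusted p = 0.444 with an estimated correlation), with Cxcl10 at 561 ± 172 against 5774 ± 2657. Cxcl1, a neutrophil chemoattractant, rose from 2108 ± 549.7 to 6503 ± 3468, a call lost in 2 of 20 alternatives. Interferon-stimulated genes fell in 6 of 22, Irf7 by a log2 change of -1.47 and Oas3 by -1.44 (camera adjusted p = 4.00e-06, and adjusted p = 0.507 with an estimated correlation). Pattern recognition receptors fell in 9 of 21 and rose in 2 (camera adjusted p = 4.00e-06, and adjusted p = 0.00482 with an estimated correlation). Clec4n was 2408 ± 692 against 17121 ± 2143 and Nod1 574 ± 3.03 against 2449 ± 432, while Mrc1, the mannose receptor, was 17989 ± 2966 against 4544 ± 439. Classical monocyte genes fell in 5 of 14 (camera adjusted p = 0.00181, and adjusted p = 0.0284 with an estimated correlation), Mgst1 from 14362 ± 429 to 2528 ± 188 and Clec4e from 25051 ± 2039 to 6697 ± 1360.1. Its member Cx3cr1 rose by a log2 change of 1.05, a call lost in 12 of 20 alternatives. Cholesterol synthesis genes fell in 3 of 18, Cyp51 by -1.51 and Msmo1 by -1.38, and adjusted over the list alone 1 also rose (camera adjusted p = 0.00338, and adjusted p = 0.507 with an estimated correlation). Receptors and transcription factors of macrophage growth fell in 3 of 23 and rose in 3, with Il4ra, the interleukin-4 receptor, at -2.21 and the transcription factor gene Klf2 at 1.48 (camera adjusted p = 0.0478, and adjusted p = 0.507 with an estimated correlation). That list had an adjusted p of 0.157 after quantile normalization and 0.102 without the 3 arrays named above. Neutrophil genes fell in 6 of 14 and rose in 2, with S100a8 at 459 ± 149 against 2855 ± 481 (camera adjusted p = 3.09e-04, and adjusted p = 0.24 with an estimated correlation). Of lymphocyte genes followed per array, Ms4a1 was 2185, 1968 and 1228 at 18 h against 712, 822 and 914 at 4 h. Cd79b and Cd2 were also higher in every 18 h array, whereas the arrays overlapped for Ighm.

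DNA replication genes rose in 16 of 29, or 17 adjusted over the list alone (camera adjusted p = 0.00338, and adjusted p = 0.767 with an estimated correlation). Mcm2, a helicase subunit, was 1002 ± 150.4 against 206 ± 35.3 and Mcm7 1199 ± 129 against 281 ± 16.7. Genes of the resident macrophage list rose in 14 of 20, with Lyve1 at 568 ± 126 against 66.1 ± 98.8 and Rarb, a retinoic acid receptor, at 242 ± 68.2 against 24.8 ± 19.3, and F5, coagulation factor V, fell from 2673 ± 139 to 831 ± 112 (camera adjusted p = 0.00457, and adjusted p = 0.644 with an estimated correlation). Adgre1 measured 16810.5 ± 291 against 8055 ± 182 (log2 fold change 1.06, adjusted p = 2.61e-07), a call lost with a common array median and with the Gapdh 3'/5' ratio as a covariate. That ratio had a mean of 2.58 at 4 h and 1.83 at 18 h. Counts adjusted over the list alone were the same for the other lists of this comparison.

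**Figure D4:**
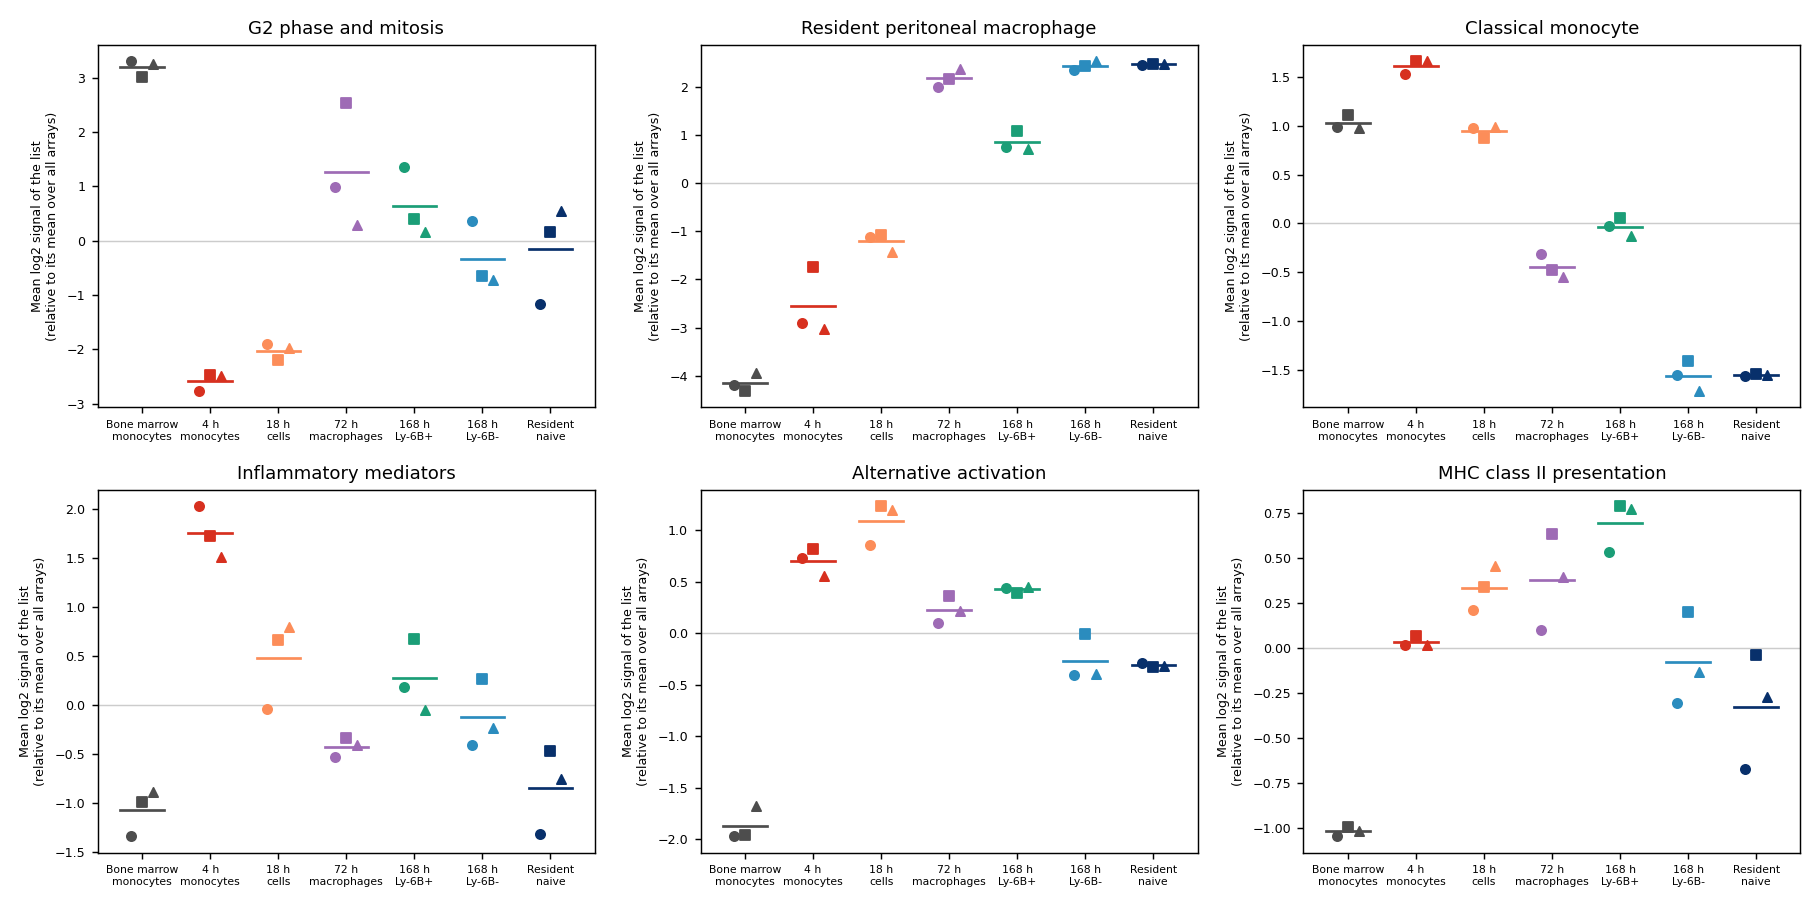
Mean log2 signal of the measured genes of 6 lists in the 7 groups, relative to the mean over all arrays, 1 point per array with a marker shape for the replicate number and a short line at each group's mean. Mitosis genes are high in bone marrow, low at 4 h and 18 h and higher at 72 h, where replicate 2 lies above the others for 29 of 29 genes.

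Macrophages of 72 h were compared with cells of 18 h, for the change towards resolution. The cells of 72 h were sorted on other markers than those of 18 h, so time and gate cannot be told apart. Resident macrophages in the cavity would also meet the gate of 72 h, and their share was not measured. Timd4 measured 13914 ± 2274 at 72 h against 347 ± 107 at 18 h (log2 fold change 5.30, adjusted p = 3.44e-10), Fabp4, a fatty acid binding protein, 14550.2 ± 3066 against 341 ± 13.6, and Sult1a1, a sulfotransferase, 2906 ± 903 against 26.7 ± 25.6. Vcan fell to 282 ± 73.2 from 7358 ± 1237, Il1b to 282 ± 207 from 4279 ± 1395, and Gsn, gelsolin, to 610.3 ± 287 from 9033 ± 1151. In all, 1094 genes were higher and 414 lower, and 41% of genes had arrays that did not overlap, against 10% by chance.

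The resident macrophage list rose in 18 of 20 (camera adjusted p = 3.79e-22, and adjusted p = 0.0254 with an estimated correlation), with Tgfb2 at 10834 ± 2494 against 330.1 ± 45.5. All 29 measured mitosis genes rose (camera adjusted p = 1.55e-17, and adjusted p = 0.292 with an estimated correlation). Ube2c, which acts in mitotic protein breakdown, measured 1382 ± 1386 against 45.1 ± 34.8 and Ccnb2, a cyclin, 2139 ± 1654 against 100.3 ± 52.1. DNA replication genes rose in 23 of 29, Rrm2 by a log2 change of 3.43 (camera adjusted p = 1.19e-09, and adjusted p = 0.438 with an estimated correlation). Each of the 29 measured mitosis genes and each of the 29 DNA replication genes was highest in 72 h replicate 2, where Mki67 was 11519 beside 4757 and 2411. Without that array 28 mitosis genes were called. In the same array Ighm, an immunoglobulin gene, was 8016 beside 457 and 498, and Cpa3, a mast cell protease gene, 3408 beside 140.0 and 131. At 18 h Ighm was 3029, 2893 and 2189. The B cell list had 0 of 12 members called (camera adjusted p = 0.332), and without the 3 arrays it was lower at 72 h (camera adjusted p = 2.28e-05, and adjusted p = 0.24 with an estimated correlation).

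Lysosomal genes rose in 3 of 22, with Glb1 at 8788 ± 1466 against 999 ± 33.8 and Gpnmb at 779.8 ± 286 against 186 ± 71.8, a call lost in 1 of 20 alternatives (camera adjusted p = 0.0143, and adjusted p = 0.425 with an estimated correlation). Classical monocyte genes fell in 8 of 14, Ms4a4c from 8159 ± 772 to 406 ± 151, while Mgst1 rose from 2528 ± 188 to 11576 ± 1392 (camera adjusted p = 5.15e-04, and adjusted p = 0.0254 with an estimated correlation). Inflammatory mediators fell in 8 of 22, Ccl12 by a log2 change of -3.55 (camera adjusted p = 0.00482, and adjusted p = 0.524 with an estimated correlation). The list's only rise was Cxcl1, by 1.09, a call lost in 10 of 20 alternatives. Alternative activation genes fell in 4 of 16, Chil3 from 20843 ± 1431 to 2085 ± 440.0 and Mrc1 from 17989 ± 2966 to 3260.3 ± 815 (camera adjusted p = 6.39e-04, and adjusted p = 0.0842 with an estimated correlation). Cholesterol synthesis genes fell in 6 of 18, Sqle from 1648 ± 392 to 177 ± 38.7 (camera adjusted p = 7.33e-06, and adjusted p = 0.181 with an estimated correlation). Glycolysis and hypoxia genes fell in 6 of 21, Slc2a1 by -1.53 and Vegfa, a vascular growth factor, by -1.89 (a call lost in 1 of 19 alternatives), and Egln3, an oxygen sensor, rose by 1.48 (camera adjusted p = 5.28e-05, and adjusted p = 0.0537 with an estimated correlation). Immediate early and heat shock genes, listed as signs of handling stress, fell in 2 of 18 (camera adjusted p = 0.0106, and adjusted p = 0.524 with an estimated correlation), Nr4a1 by -1.58 and Hsph1 by -1.54. Members without a call included Fos, which was 18921 ± 965 at 72 h and 22624 ± 2258 at 18 h, and Dusp1 26104 ± 1413 and 26231 ± 2905. For each list named, the count adjusted over the list alone was that over all genes.

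At 168 h the Ly-6B+ macrophages were compared with the Ly-6B- macrophages of the same time. Ccr2 measured 6848 ± 1173 against 160.0 ± 65.4 (log2 fold change 5.35, adjusted p = 3.18e-09) and Chil3 17871 ± 4519.9 against 908 ± 687. Ltb4r1, a leukotriene B4 receptor, was 251 ± 71.3 against 21.3 ± 16.2 and Plac8 11564 ± 1969 against 1622 ± 646. Garnl3 was 183 ± 83.4 against 4156 ± 527 (log2 fold change -4.47), Wnt2, a secreted signalling protein, 381 ± 144 against 6990.0 ± 845, and Hdc, the enzyme that makes histamine, 165 ± 45.2 against 3176 ± 286. In all, 181 genes were higher and 289 lower in the Ly-6B+ group, and the arrays did not overlap for 25.1% of genes, where chance gives 10%. The Gapdh 3'/5' ratio was 2.89, 2.17 and 2.59 in the Ly-6B+ arrays and 2.42, 1.94 and 2.36 in the Ly-6B- arrays of the same numbers. With that ratio as a covariate 153 of the genes higher and 250 of those lower kept their call. Arrays of these groups with the same replicate number were taken as pairs, with r across genes of 0.304, 0.280 and 0.175 for arrays of the same number after the group means were removed. With the replicate block in the fit, 185 genes were higher and 300.0 lower, and with only the 6 arrays and the block, added after seeing the data, 246 and 330.0.

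Classical monocyte genes rose in 7 of 14 (camera adjusted p = 3.01e-09, and adjusted p = 2.92e-04 with an estimated correlation). MHC class II genes rose in 6 of 14, H2-Eb1 from 7726 ± 3527 to 27041 ± 3386 and H2-Ab1 from 7628 ± 3454 to 24911 ± 3453 (camera adjusted p = 2.52e-05, and adjusted p = 0.168 with an estimated correlation). Alternative activation genes rose in 4 of 16, or 5 adjusted over the list alone, with Retnla at 19335 ± 6433 against 4029 ± 534 (camera adjusted p = 0.00736, and adjusted p = 0.184 with an estimated correlation). The resident macrophage list fell in 11 of 20 (camera adjusted p = 2.38e-16, and adjusted p = 0.0501 with an estimated correlation), Vsig4, a complement receptor, from 22476 ± 3662 to 1682 ± 692. Lysosomal genes fell in 2 of 22, Glb1 from 8712 ± 1344 to 3009 ± 256 and Gpnmb from 528 ± 159 to 174 ± 33.7, a call lost in 4 of 20 alternatives (camera adjusted p = 1.25e-07, and adjusted p = 0.0501 with an estimated correlation). The mitosis list had a median log2 change of 1.03 with 0 of 29 members called (camera adjusted p = 1.47e-07, and adjusted p = 0.516 with an estimated correlation), and the DNA replication list a median of 0.74 with 0 of 29 called (camera adjusted p = 5.86e-08, and adjusted p = 0.516 with an estimated correlation). Cholesterol synthesis genes had a median of 0.15 with 0 of 18 called (camera adjusted p = 0.0308, and adjusted p = 0.516 with an estimated correlation). With the replicate block these 3 lists had an adjusted p of at most 0.0313, the value of the cholesterol list. The block over all 21 arrays gave 0 mitosis, 1 DNA replication and 0 cholesterol members called higher. With only the 6 arrays and the block, 17, 4 and 0 were called higher. Among markers of other cells, neutrophil genes rose in 4 of 14 (camera adjusted p = 0.00736, and adjusted p = 0.379 with an estimated correlation), with S100a8 at 582 ± 135 against 226 ± 80.5, a call lost in 11 of 20 alternatives. The B cell list had a median of 0.81 with 0 of 12 called (camera adjusted p = 0.0161, and adjusted p = 0.571 with an estimated correlation), or 4 with the 6 arrays and the block. Ighm, for which 2 of 6 other probe sets changed in the opposite direction without a call here and in each later comparison that names it, was 1740.4 ± 285 against 809.8 ± 147, and Ms4a1, which encodes CD20, 1119.7 ± 561 against 423 ± 93.1. T and NK cell genes had 1 of 8 called, 2 adjusted over the list alone, and an adjusted p of 0.095, or 0.0329 without bone marrow replicate 3, 4 h replicate 2 and 72 h replicate 2 (0.182 with an estimated correlation). With the replicate block over all 21 arrays 0 of them were called, 1 adjusted over the list alone, and with the 6 arrays and the block 2. Adjusted over the list alone, the other lists named here had the same counts.

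Members of the resident macrophage list differed in how much of the Ly-6B- level the Ly-6B+ macrophages held in arrays of the same number. Garnl3 stood at 4.45% ± 2.06 (SD, n = 3), Vsig4 at 7.72% ± 3.67 and Timd4 at 9.57% ± 2.50 of the Ly-6B- level. Gata6, a transcription factor of resident peritoneal macrophages, stood at 42.5% ± 7.48 and F5 at 44.3% ± 0.969. Alox15 stood at 84.4% ± 9.82, Fcna, a ficolin, at 81.7% ± 3.79 and F10, coagulation factor X, at 96.7% ± 5.24. Percentages were computed from signals, for genes of a list fixed before the data were examined.

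**Figure D5:**
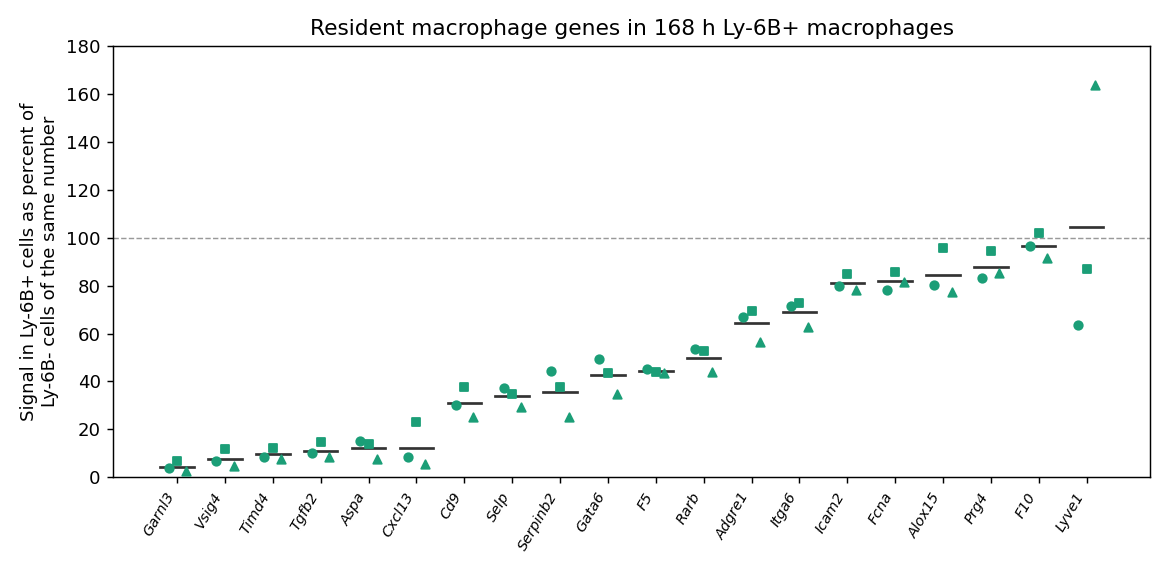
Signal in Ly-6B+ macrophages at 168 h as a percentage of that in Ly-6B- macrophages for the 20 measured resident macrophage genes, 1 point per pair of arrays with the same number, a marker shape for that number, a short line for the mean and a dashed line at 100%. Means run from 4.45% for Garnl3 to 105% for Lyve1, whose pairs spread with an SD of 52.4.

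Ly-6B- macrophages of 168 h were compared with resident macrophages of naive mice, for what differed a week after zymosan. The gate does not tell recruited cells from resident macrophages still in the cavity or returned to it, and the origin of the cells was not tested. A small number of differences therefore does not show that recruited cells came to resemble resident ones. Limma called 5 genes higher and 0 lower, and 428 genes had an unadjusted p under 0.05. That is fewer than a share of 0.05 of the 12154 genes tested, which chance alone would give. The arrays did not overlap for 8.57% of genes, where chance gives 10%. Flrt3, a membrane protein gene, measured 109 ± 42.4 against 7.90 ± 6.87 (log2 fold change 2.43, adjusted p = 0.012), Vegfa 164 ± 34.6 against 26.7 ± 19.5 (2.17, adjusted p = 0.00477) and Basp1 477 ± 121 against 144 ± 19.4 (1.60, adjusted p = 0.00477). Mmp14, a membrane metalloproteinase, measured 262 ± 41.2 against 86.0 ± 3.22 (1.45, adjusted p = 0.00259), and Noct 601 ± 111 against 236 ± 24.6 (1.28, adjusted p = 0.00595). The number higher ran from 2 without Ly-6B- replicate 2 to 7 without Ly-6B- replicate 1 and came to 0 with only the 6 arrays of both groups fitted. Of the 5 genes, 2 kept their call with the mean of their probe sets. Calls were lost in 6 of 20 alternatives for Flrt3, 3 of 19 for Vegfa (log2 change down to 0.70), 3 of 20 for Basp1, 3 of 20 for Noct and 2 of 20 for Mmp14.

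The glycolysis and hypoxia list rose with 1 of 21 members called, Vegfa (camera adjusted p = 6.73e-05, and adjusted p = 0.148 with an estimated correlation). Inflammatory mediators had a median log2 change of 0.76 with 0 of 22 called, or 5 adjusted over the list alone (camera adjusted p = 1.01e-12, and adjusted p = 0.166 with an estimated correlation). Interferon-stimulated genes had a median of 0.23 with 0 of 22 called (camera adjusted p = 6.73e-05, and adjusted p = 0.704 with an estimated correlation), the B cell list 0.49 with 0 of 12 (camera adjusted p = 0.0399, and adjusted p = 0.724 with an estimated correlation), and the ribosomal protein list -0.11 with 0 of 16 (camera adjusted p = 0.00208, and adjusted p = 0.723 with an estimated correlation). After quantile normalization the ribosomal list had an adjusted p of 0.059. Ighm measured 809.8 ± 147 against 549 ± 114 and Rps2, a ribosomal protein gene, 28849.7 ± 1533 against 30994 ± 1892. Of the resident macrophage list 0 of 20 members were higher and 0 lower, with a median of -0.07 (camera adjusted p = 0.983). T and NK cell genes had an adjusted p of 0.0665, or 0.014 without the 3 arrays named above (0.208 with an estimated correlation). A p that misses the threshold does not show that the levels were equal.

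Ly-6B+ macrophages of 168 h against resident macrophages gave 231 genes higher and 287 lower, with arrays that did not overlap for 27.9% of genes, against 10% by chance. Chil3 measured 17871 ± 4519.9 against 285 ± 67.5 (log2 fold change 5.89, adjusted p = 6.02e-09), Ccr2 6848 ± 1173 against 182 ± 118 and Kcnn4, a potassium channel, 1097 ± 112 against 56.6 ± 27.7. Garnl3, Tox2 and Wnt2 changed by -4.50, -4.50 and -4.25 on the log2 scale. Classical monocyte genes rose in 6 of 14 (camera adjusted p = 7.81e-07, and adjusted p = 0.0019 with an estimated correlation) and MHC class II genes in 7 of 14, H2-Ab1 by 2.61 (camera adjusted p = 9.89e-07, and adjusted p = 0.0807 with an estimated correlation). Inflammatory mediators rose in 9 of 22, or 11 adjusted over the list alone, Cxcl9 from 33.0 ± 39.7 to 466 ± 340.4 (camera adjusted p = 8.47e-08, and adjusted p = 0.204 with an estimated correlation). Alternative activation genes rose in 4 of 16 (camera adjusted p = 0.00448, and adjusted p = 0.162 with an estimated correlation), and the cholesterol list had Sqle alone called, at 1.05, a call lost in 6 of 20 alternatives (camera adjusted p = 0.0186, and adjusted p = 0.471 with an estimated correlation). Genes of the resident macrophage list fell in 11 of 20 (camera adjusted p = 2.40e-15, and adjusted p = 0.0807 with an estimated correlation) and the lysosomal list in 1 of 22, Glb1 (camera adjusted p = 1.14e-05, and adjusted p = 0.0807 with an estimated correlation).

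In the same comparison the DNA replication and mitosis lists had medians of 0.74 and 0.83 with 0 members called in either (camera adjusted p = 2.07e-07 and 1.54e-05, and adjusted p = 0.452 and 0.499 with an estimated correlation). Markers of other cells were higher as well. The B cell list had 0 of 12 called and 5 adjusted over the list alone, with Ighm at 1740.4 ± 285 against 549 ± 114 (camera adjusted p = 1.58e-04, and adjusted p = 0.403 with an estimated correlation). T and NK cell genes rose in 3 of 8, Cd2 from 52.7 ± 35.1 to 320.2 ± 73.5, a call lost in 4 of 19 alternatives (camera adjusted p = 0.00465, and adjusted p = 0.333 with an estimated correlation), and neutrophil genes in 2 of 14, or 3 adjusted over the list alone (camera adjusted p = 0.0218, and adjusted p = 0.403 with an estimated correlation). Handling stress genes rose in 1 of 18, Atf3 by 1.23 (camera adjusted p = 0.00973, and adjusted p = 0.471 with an estimated correlation), and Fos, without a call, was 23321 ± 2364 against 24292 ± 2402. Ribosomal protein genes had a median of -0.17 with 0 of 16 called (camera adjusted p = 0.0205, and adjusted p = 0.601 with an estimated correlation), and the list's adjusted p was 0.893 after quantile normalization. Lists not given a second count had the same one adjusted over the list alone.

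Macrophages of 72 h against resident macrophages gave 81 genes higher and 3 lower, with arrays that did not overlap for 15.4% of genes, against 10% by chance. Without 72 h replicate 3 the counts were 161 and 25, without 72 h replicate 2 the number higher was 54, and without 72 h replicate 1 the number lower was 1. Ccr2 measured 5288 ± 2687 against 182 ± 118 (log2 fold change 4.80, adjusted p = 2.33e-08), Ltb4r1 454 ± 165 against 6.17 ± 1.66 and Ctla2a 1976 ± 539.7 against 113 ± 38.6. Lower at 72 h were Hes1, a target of Notch signalling (-1.33), Fscn1 (-1.66) and Prkar1b (-1.76), calls lost in 5 of 20, 7 of 20 and 4 of 19 alternatives. Prkar1b came to -0.28 with the mean of its probe sets. Of its 3 other probe sets, 2 changed in the opposite direction without a call. Classical monocyte genes rose in 6 of 14 (camera adjusted p = 5.67e-08, and adjusted p = 7.48e-04 with an estimated correlation), chemoattractant receptors and adhesion genes in 4 of 22 (camera adjusted p = 6.78e-05, and adjusted p = 0.0367 with an estimated correlation), and alternative activation genes in 2 of 16, Chil3 by 2.81 (camera adjusted p = 4.39e-05, and adjusted p = 0.0391 with an estimated correlation). Through Ccr2 and Chil3 these lists share members, so they are not separate findings. MHC class II genes rose in 2 of 14, or 4 adjusted over the list alone, H2-Eb1 from 5409 ± 2708 to 19413 ± 4614 (camera adjusted p = 3.81e-07, and adjusted p = 0.051 with an estimated correlation). Inflammatory mediators rose in 2 of 22, Ccl5 by 3.88 (camera adjusted p = 0.0206, and adjusted p = 0.593 with an estimated correlation), and glycolysis and hypoxia genes in 1 of 21, Slc2a1 by 1.22 (camera adjusted p = 6.78e-05, and adjusted p = 0.051 with an estimated correlation).

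The mitosis list at 72 h had a median log2 change of 1.42 against resident macrophages with 0 of 29 members called and 28 adjusted over the list alone (camera adjusted p = 8.14e-24, and adjusted p = 0.149 with an estimated correlation). DNA replication genes had a median of 0.74 with 0 called and 7 adjusted over the list alone (camera adjusted p = 5.04e-14, and adjusted p = 0.23 with an estimated correlation). Without 72 h replicate 2 the mitosis median was 0.78 and 0 members were called adjusted over the list alone (camera adjusted p = 8.76e-13, and adjusted p = 0.391 with an estimated correlation). In that array Ms4a1 was 5384 beside 267 and 289, and Cd2 1089 beside 115 and 89.8. The B cell list had 0 of 12 called (camera adjusted p = 4.64e-05, and adjusted p = 0.36 with an estimated correlation) and the T and NK cell list 1 of 8, or 2 adjusted over the list alone (camera adjusted p = 4.48e-04, and adjusted p = 0.186 with an estimated correlation). With 3 arrays left out, that one among them, these adjusted p values were 0.551 and 0.138. The resident macrophage list had a median of -0.30 with 0 of 20 called (camera adjusted p = 0.0206, and adjusted p = 0.593 with an estimated correlation) and an adjusted p of 0.17 after quantile normalization. Handling stress and ribosomal protein lists had medians of -0.33 and -0.21 with 0 called in either (camera adjusted p = 8.29e-04 and 5.38e-05, and adjusted p = 0.44 and 0.443 with an estimated correlation).

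Ly-6B+ macrophages of 168 h against macrophages of 72 h gave 81 genes higher and 225 lower, with arrays that did not overlap for 19.2% of genes, against 10% by chance. The gate at 72 h did not split cells by Ly-6B, so time and gate cannot be told apart. Chil3 measured 17871 ± 4519.9 against 2085 ± 440.0 (log2 fold change 3.08, adjusted p = 4.91e-05) and Cd177 1309 ± 201 against 246 ± 10.5. Ctla2a stood at 53.0 ± 8.21 against 1976 ± 539.7 and Hdc at 165 ± 45.2 against 2934 ± 353. The resident macrophage list fell in 10 of 20 (camera adjusted p = 3.81e-16, and adjusted p = 0.0783 with an estimated correlation) and the lysosomal list in 2 of 22, Gpnmb by a log2 change of -2.02, a call lost in 1 of 20 alternatives (camera adjusted p = 1.46e-10, and adjusted p = 0.025 with an estimated correlation). Inflammatory mediators rose in 2 of 22, or 5 adjusted over the list alone, Cxcl10 by 2.11 (camera adjusted p = 3.83e-05, and adjusted p = 0.493 with an estimated correlation), and handling stress genes in 3 of 18 (camera adjusted p = 9.16e-09, and adjusted p = 0.218 with an estimated correlation). The mitosis list had a median of -0.61 with 0 of 29 called (camera adjusted p = 5.28e-04, and adjusted p = 0.577 with an estimated correlation) and an adjusted p of 0.893 without the 3 arrays named above. With those left out, markers of other cells were higher in Ly-6B+ macrophages. The camera adjusted p was 1.86e-09 for B cells, 0.0135 for T and NK cells, 0.0157 for progenitors and 0.0425 for neutrophils. With an estimated correlation the adjusted p was 0.138 or more for each of these lists. Respiratory chain genes had a median of -0.13 with 0 of 26 called (camera adjusted p = 0.0174, and adjusted p = 0.577 with an estimated correlation), and an adjusted p of 0.2 after quantile normalization.

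Ly-6B- macrophages of 168 h against macrophages of 72 h gave 7 genes higher and 52 lower, with arrays that did not overlap for 12.9% of genes, against 10% by chance. Here too the cells of 72 h were not split by Ly-6B, so time and gate cannot be told apart. Without 72 h replicate 3 the counts were 14 and 125, without 72 h replicate 2 the number lower was 37, and without Ly-6B- replicate 1 the number higher was 2. Ccr2 measured 160.0 ± 65.4 against 5288 ± 2687 (log2 fold change -4.87, adjusted p = 5.02e-08), Ltb4r1 21.3 ± 16.2 against 454 ± 165, and Hes1 3848 ± 634 against 1208 ± 221. Classical monocyte genes fell in 4 of 14, or 6 adjusted over the list alone (camera adjusted p = 1.46e-12, and adjusted p = 5.40e-05 with an estimated correlation). Alternative activation genes fell in 2 of 16, or 4 adjusted over the list alone, Retnla from 14475 ± 5055 to 4029 ± 534 (camera adjusted p = 2.39e-05, and adjusted p = 0.0483 with an estimated correlation). Chemoattractant receptors and adhesion genes fell in 3 of 22, or 4 adjusted over the list alone (camera adjusted p = 0.00162, and adjusted p = 0.0822 with an estimated correlation). MHC class II genes had 0 of 14 called and 1 lower adjusted over the list alone, with a median of -0.65 (camera adjusted p = 2.52e-04, and adjusted p = 0.223 with an estimated correlation). Inflammatory mediators had a median of 0.50 with 1 lower, and adjusted over the list alone 1 was also higher (camera adjusted p = 0.0192, and adjusted p = 0.687 with an estimated correlation). Handling stress genes had a median of 0.57 with 0 of 18 called and 1 adjusted over the list alone (camera adjusted p = 1.30e-06, and adjusted p = 0.223 with an estimated correlation). For resident macrophage genes the list had a median of 0.21 with 0 of 20 called (camera adjusted p = 0.0192, and adjusted p = 0.687 with an estimated correlation).

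Mitosis genes in that comparison had a median of -1.56, with 1 of 29 lower, Ccnb2 (a call lost in 8 of 20 alternatives), and 29 adjusted over the list alone (camera adjusted p = 2.59e-29, and adjusted p = 0.134 with an estimated correlation). DNA replication genes had a median of -0.83 with 0 called, and adjusted over the list alone 9 were lower and 1 was higher (camera adjusted p = 3.66e-15, and adjusted p = 0.226 with an estimated correlation). Without 72 h replicate 2 the mitosis median was -0.94 and 0 members were called adjusted over the list alone (camera adjusted p = 4.46e-18, and adjusted p = 0.329 with an estimated correlation). B cell, neutrophil and respiratory chain lists had medians of -0.55, -0.30 and -0.08 with 0 members called in each (camera adjusted p = 0.0242, 0.0192 and 0.0192, and adjusted p = 0.687, 0.437 and 0.687 with an estimated correlation). Ighm was 809.8 ± 147 against 2990.3 ± 4353 in this comparison, and 72 h replicate 2 held the 8016 given above. Without the 3 arrays named before, the B cell list was higher in place of lower, with an adjusted p of 0.0251 (0.566 with an estimated correlation), and the neutrophil list had 0.0601. Over the 10 comparisons 4 cell type lists had no call, with a smallest camera adjusted p of 0.0701 for dendritic cells, 0.0926 for mast cells, 0.135 for erythroid cells and 0.231 for platelets. Without the 3 arrays the platelet list was lower in Ly-6B+ macrophages of 168 h than at 72 h (adjusted p = 0.044, and adjusted p = 0.291 with an estimated correlation). The eosinophil and mesothelial or fibroblast lists had 2 and 4 measured genes and were not tested as lists. Prg2 and Alox15 are the measured eosinophil genes, the latter also a resident macrophage gene. Krt8, Col1a2, Dcn and Sparc of the mesothelial or fibroblast list had an adjusted p of 0.144 or more in each of the 10 comparisons, the lowest that of Krt8 at 4 h against bone marrow.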

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

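The alternative that leaves out 3 arrays, the fit of only the 6 arrays with the block at 168 h, and the alternatives for reference means and array correlations were chosen after seeing the data, and the others before. Of the gene counts under all alternatives, 392 were within 1.5 times the value reported, 46 were above and 38 below that. Log2 changes of named genes and reference genes kept their side of the threshold in 8110 cases, gained a call in 54 and lost it in 192. None of those called in the main fit changed direction, and changes of sign among genes without a call were not counted. Over 4 alternatives the 110 list calls held in 335 of 440 cases, were lost in 104 and turned in 1, and 34 calls were gained. With an estimated correlation 21 of 110 list calls were left. Of the reference means 217 moved by less than 1 SD and 21 by more, and of the array correlations 26 and 37. Signals near the array background limit each fold against a group that lacks a gene.

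Counts moved by over 1.5 times are given as higher/lower, and the cause was not tested unless said. A common array median gave 1598/1110 for 4 h against bone marrow and 731/985 for 18 h against 4 h, a shift of all genes by construction. Counting all probe sets, which are more than the genes, gave 2728/2191 for resident macrophages against bone marrow, 1779/2787 for 4 h, 2033/1040 for 18 h, 1768/745 for 72 h against 18 h, 300.0/446 for Ly-6B+ against Ly-6B-, 414/438 for Ly-6B+ against resident, 5 lower for 72 h against resident, 145 higher for Ly-6B+ against 72 h, 11/80.0 for Ly-6B- against 72 h, and 14737 in the F test. No minimum fold, a wider rule, gave 3073/2691, 1996/3662, 3340.0/1519 and 2118/1568 for the first 4 of these, 427/557 at 168 h, 1 lower for Ly-6B- and 497/595 for Ly-6B+ against resident, 124/12 for 72 h against resident, 223/390.0 for Ly-6B+ and 11 higher for Ly-6B- against 72 h. Limma's treat, a stricter rule, gave 816/590.0, 440.0/827, 339/161, 426/110.0 and 28/68 in that order. It gave 0 higher for Ly-6B-, 32/69 for Ly-6B+ and 15/0 for 72 h against resident. Against 72 h it gave 2/52 for Ly-6B+ and 0/10 for Ly-6B-. The main fit, without treat, had 428 genes at an unadjusted p under 0.05 for Ly-6B- against resident.

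The filter at the 75th percentile tests fewer genes and gave 1026 higher in resident macrophages against bone marrow, 185 lower in Ly-6B+ against Ly-6B-, 186 lower in Ly-6B+ against resident and 3 higher in Ly-6B- against 72 h. The mean of probe sets gave 51 higher in Ly-6B+ and 4 higher in Ly-6B- against 72 h. For 72 h against resident, 4 times the pseudocount gave 8 lower, array weights 5 and the replicate block 6, and the block gave 11 higher for Ly-6B- against 72 h. Only the 6 arrays, with fewer degrees of freedom, gave 0 higher for Ly-6B- against resident, 44 higher for 72 h against resident and 24 lower for Ly-6B- against 72 h. Without bone marrow replicate 3, 4 h replicate 2 and 72 h replicate 2, Ly-6B- against 72 h gave 4/34, and its B cell list was higher in place of lower with an adjusted p of 0.0251. Leaving out 1 replicate gave 2 to 7 higher and 0 to 2 lower for Ly-6B- against resident, 54 to 161 higher and 1 to 25 lower for 72 h against resident, and 2 to 14 higher and 37 to 125 lower for Ly-6B- against 72 h.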

Other observations

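Genes were also sorted by the group with their highest mean, a view chosen after the values were seen. Of the 8477 genes that differed in the F test, 1689 were highest at 4 h, and 271 of these led the next group by at least 1 on the log2 scale. Gcnt2, a glycosyltransferase gene, led by 4.64 with a signal of 11417 ± 248 (SD, n = 3), and Sphk1, sphingosine kinase, by 4.41. At 18 h 982 genes were highest, with Scd2, a fatty acid desaturase, leading by 1.98 at 6225 ± 1005 and Crip2 by 1.94. At 72 h 441 genes were highest and 2 led by at least 1, Ctla2a by 2.39 and Saa1, serum amyloid A, by 1.52. In the Ly-6B+ macrophages of 168 h 617 genes were highest and 6 led by at least 1. They were F7, coagulation factor VII, by 1.12 at 6215 ± 402, Scarf1 by 1.09, F3, tissue factor, by 1.09, Egr3 by 1.06, Jam2 by 1.03 and Gbp8 by 1.02. Bone marrow monocytes held 2186 of the highest means, resident macrophages 1443 and Ly-6B- macrophages of 168 h 1119, and 0 genes of the last 2 groups led by at least 1. Arrays of these 2 groups correlated with each other at a mean r of 0.976, and a gene high in both leads by little. The 0 therefore does not show that they lack distinctive genes.

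The tests of cells or transcripts carried over, of the array ceiling and of 72 h replicate 2 on the mitosis genes were chosen after the results they concern were seen. The test of array background and the counts of splits were written before. For both carry-over tests, at 4 h over the list and at 168 h, an earlier version had been run and its outcome seen before the form reported was chosen. At 4 h the earlier version compared each called member's median share with 2.66%, which 6 of 11 exceeded, and would have excluded carry-over for the list as a whole. The later form splits the members and leaves more open. At 168 h the earlier version asked for more than 50% of the members above 37.3% in each pair, and 10 of 20 gave no exclusion. The later form does give one, so that its outcome rests on a test chosen with the per-gene values known.

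Resident macrophage genes in the 4 h monocytes were set against resident cells carried into the sort, which was gated Ly-6B+ and Ly-6G-, a gate meant for monocytes. Abundant resident transcripts outside the list, 11 in number, had a median of 0.885% of the resident level at 4 h, and the highest, Arg1, had 45.5%. Of 11 called members, 3 (F5, F10 and Serpinb2) were above 3 times the median share of that array in each of the 3 arrays, which argues against carry-over as their only source. The other 8 had a median of 1.432%, and for them carry-over and expression cannot be told apart, because a small share of cells would give such levels. Their shares differed in pattern over replicates 1, 2 and 3. Alox15 stood at 0.292%, 6.46% and 0.365% and Vsig4 at 0.0312%, 1.31% and 0.0697%. Cd9 stood at 5.01%, 6.27% and 4.31% and Selp at 2.62%, 3.42% and 3.15%. These members were not tested singly. In 4 h replicate 2, 90.91% of the abundant resident transcripts (10 of 11) were highest of the 3 arrays, which is what carried resident macrophages may give in that array.

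In the Ly-6B+ macrophages of 168 h the resident genes stood at unequal percentages of the Ly-6B- level. The upper quartile of the members was 5.21, 4.07 and 9.43 times the lower in the 3 pairs, and the smallest, 4.067, argues against 1 common share of Ly-6B- cells as the sole source of all members. Given how that test was chosen, and the 10 of 20 under the earlier bound, a share of carried cells beside cells that express part of the list stays open, as does a Ly-6B+ gate that holds several kinds of macrophage. A ceiling of the array signal could hide differences among the abundant members. Of 6 members with a Ly-6B- mean under the signal minimum set for that test, 1 (Lyve1) kept more than 50% in each pair, so that test cannot decide. Timd4 (Ly-6B- mean 16913), Vsig4 (22476) and Cxcl13 (27721) stood at 9.57%, 7.72% and 12.35%. F10 (15772), Fcna (18137) and Icam2 (20455) stood at 96.7%, 81.7% and 80.9%. These values argue against a ceiling common to all genes as the source of that split. Garnl3 (4156) and Aspa (6164) were low in both. Ceilings of single probe sets stay open, as does a ceiling near the signals of Alox15 (31509.5) and Prg4 (32926.5).

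Lymphocyte and mast cell transcripts stood out in 72 h replicate 2, a sort gated on F4/80 and CD11b. Array background does not account for them, since low genes moved by 14.89% of the shift of the B cell list (0.386 of 2.59 on the log2 scale, over 1158 low genes chosen from the other arrays, a choice that favours background). Carried cells in that array are not the whole of the rise of mitosis genes from 18 h, as 28 of 29 were called without it. Above resident macrophages the mitosis median without it was 0.7792 in place of 1.415, and that rest does not come from cells of that array. Whether a rise stands without it cannot be told apart from the spread between arrays, since the list level was 0.996 and 0.291 in the other 72 h arrays and -1.17, 0.150 and 0.548 in the resident ones, and 0 members were called adjusted over the list alone. More division in the macrophages of that sample is a candidate explanation and was not tested.

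Other groupings of the same arrays were counted. For 3 arrays against 3 there are 10 splits, or 4 that part the pairs at 168 h, too few for a share under 0.05. The real split gave 1559 higher and 1229 lower for resident macrophages against bone marrow, with 1 as the highest other. It gave 905 and 1759 at 4 h (highest other 2), 1320.0 and 544 at 18 h (2), 1094 and 414 at 72 h (0), and 181 and 289 at 168 h (1). Against resident macrophages it gave 5 and 0 for Ly-6B- (1, and 10 splits had at least 0 lower), 231 and 287 for Ly-6B+ (1), and 81 and 3 at 72 h (0). Against 72 h it gave 81 and 225 for Ly-6B+ (0), and 7 and 52 for Ly-6B- (8, and 2 splits had at least 7 higher). In the F test 1 of 100.0 groupings of the 21 arrays, the real one, gave as many as 8477 genes, the highest other being 1566. That makes chance an unlikely source, but so few groupings cannot exclude it. They were drawn without regard to replicate numbers.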
